A study of Mus musculus with 6 samples.

How the data were processed

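Polyadenylated RNA was measured in 6 libraries of B16-OVA cells, 3 WT and 3 Ythdf2-KO. Per the labels' protocols, RNA was isolated with TRIzol and enriched for poly(A) with Dynabeads, libraries were made with the KAPA RNA HyperPrep kit, and an Illumina NovaSeq instrument read them as paired ends. Per the submitters' processing notes, the authors trimmed reads with fastp 0.23.2, aligned them with HISAT2 2.2.1 to GRCm39 and counted them per gene with featureCounts 2.0.6. The deposited values are these whole counts per gene symbol, with no normalization by the authors. The settings for strand and for reads with several alignments are not given in the sources used here, so antisense and overlapping genes cannot be told apart and near-identical copies can share counts. This concerns MHC class I paralogs, ribosomal protein genes and Gapdh with their pseudogenes, histone genes, Aldh1a7, Saa3 and low mitochondrial mRNAs.

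The table held 56734 gene symbols, 24228 of them with no count in any library. Columns were assigned to groups by the labels alone. The libraries detected 24998 to 25913 genes, and a count of 3 equalled 0.0432 to 0.0539 CPM, so genes at a few counts carry large counting error. The 20 most abundant genes took 8.60 to 10.3% of the counts and the ribosomal RNA gene Rn18s-rs5 1.32 to 2.36%. Mitochondrially encoded genes took 1.16, 1.08 and 1.33% in WT and 1.82, 1.81 and 1.57% in Ythdf2-KO.

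Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings, which left 17718, and scaled with TMM factors of 0.981 to 1.02. A quasi-likelihood model with robust dispersions compared the genotypes, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, and folds of 2 were read from the fitted log2 fold change; log2 CPM for the list tests used a prior count of 2. Levels are means ± SD of TMM-scaled CPM over 3 libraries. Where a group held 1 to 3 counts in total, the ratio of summed counts over effective library sizes is given. Its 95% interval covers counting error only and takes counts as independent. If the 2 reads of a pair were counted singly, which was not checked, the interval is too narrow. The 25 gene lists were fixed before the data were examined and tested with camera in limma 3.58.1 at a correlation of 0.01, with Benjamini-Hochberg adjustment over lists. The grouping, tests, thresholds, alternatives and rule for named genes were also chosen before the data were examined. That rule took the targeted gene and 10 further genes given in advance, the 10 largest rises and 10 largest falls among called genes with a mean of at least 100 counts in the higher group, no overlap between the genotypes' libraries and an established symbol, and the 4 members of each list with the smallest adjusted p, of which a few are not reported here. Other named genes were chosen after their values were seen.

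The pipeline was tested on counts simulated from the fitted model, with 50 genes changed at each fold and 17495 left unchanged. The changed genes were drawn without those at low levels. The pipeline recovered 80% of genes changed 1.2-fold, 88% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 13 false calls. In the real comparison far more genes differed, many of them at low levels, so these rates need not hold there. Replicates were checked against each other by a chi-square per degree of freedom on counts, which was 4.22 to 14.6 within a genotype and 116 to 136 between genotypes, and the first principal component held 71.2% of the variance.

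The alternatives were RLE and upper-quartile scaling, no filter and a filter at a mean of 5 CPM, scaling without the 20 most abundant and the mitochondrial genes, the replicate block, leaving out each library, the Wald test of DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, offsets for transcript length and GC content, and camera with an estimated correlation or fry for lists. Leaving out replicate 3 of both genotypes was added after the data were seen. Gene positions, transcript lengths, GC content and 3-prime UTRs came from GENCODE and RefSeq annotation of GRCm38, joined by symbol, because the build differs from that of the counts; no coordinates are given. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Protein, m6A sites, RNA stability and the edited sequence were not analysed here.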

Results

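Polyadenylated RNA was sequenced from B16-OVA cells, a derivative of the mouse B16 melanoma line that makes chicken ovalbumin as a model tumor antigen. The 6 libraries fell into 2 groups, 3 from WT cells and 3 from cells with a knockout of Ythdf2 (Ythdf2-KO). The titles of the WT samples carry the tag gNC, which may stand for a negative-control guide RNA, so these cells may not be unmanipulated. YTHDF2 is a cytoplasmic protein that binds mRNAs carrying N6-methyladenosine (m6A) and is known to promote their decay. The totals were 55660473, 66768830 and 68739046 counts for WT replicates 1 to 3, and 67298178, 61167059 and 69497273 for Ythdf2-KO replicates 1 to 3. Of the 56734 gene symbols in the table, 17718 had enough counts to be tested. The labels do not say whether the replicates of a genotype were separate cultures. The p-values of single genes therefore measure the spread between these libraries, whatever its source. Those of camera, of permutations over genes and of the binomial test take genes as the units.

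The comparison of Ythdf2-KO with WT asks how loss of this m6A reader alters the mRNAs of the tumor cells themselves, in a study of immune evasion by tumors. Ythdf2 mRNA was lower in every Ythdf2-KO library. It stood at 124, 124 and 125 TMM-scaled counts-per-million (CPM) in WT replicates 1 to 3 and at 100.1, 101 and 104 CPM in Ythdf2-KO replicates 1 to 3. The log2 fold change was -0.29 ± 0.018 (SE, n = 3 per group; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.08e-13), so 0.816 times the WT level remained. Gene-level counts show neither the edited sequence nor the protein. The paralog Ythdf1 fell 1.19-fold, from 160 ± 4.67 to 134 ± 0.493 CPM (SD, n = 3). Ythdf3 fell 1.09-fold, from 108 ± 3.51 to 99.5 ± 1.76 CPM. The call for Ythdf3 was lost with upper-quartile scaling (edgeR adjusted p = 0.0589) and without replicate 3 of both genotypes (edgeR adjusted p = 0.0507). The nearest tested genes with established symbols on either side of Ythdf2 on chromosome 4 were Epb41 and Gmeb1. Their log2 fold changes were -0.024 and 0.043, and neither passed the test.

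Differences between the genotypes were widespread and mostly small. At an adjusted p under 0.05, 4270 genes were higher and 4569 lower in Ythdf2-KO, together 49.9% of the genes tested. Of these, 1092 were at least 2-fold higher and 598 at least 2-fold lower, while 69.9% differed by less than 1.5-fold. Most of the genes at least 2-fold apart had a mean below 5 CPM: 408 of these 1690 genes passed a filter at a mean of 5 CPM, under which 239 genes were at least 2-fold higher and 171 lower. Replicates of a genotype lay close together, with a biological coefficient of variation of 3.48%, and 55.9% of the tested genes had every library of one genotype above every library of the other, against 10% by chance. The balance of directions depended on the scaling: 48.3% of the calls were higher in Ythdf2-KO with TMM factors, 59.2% with upper-quartile factors and 37.6% with offsets for transcript length and GC content.

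**Figure D1:**
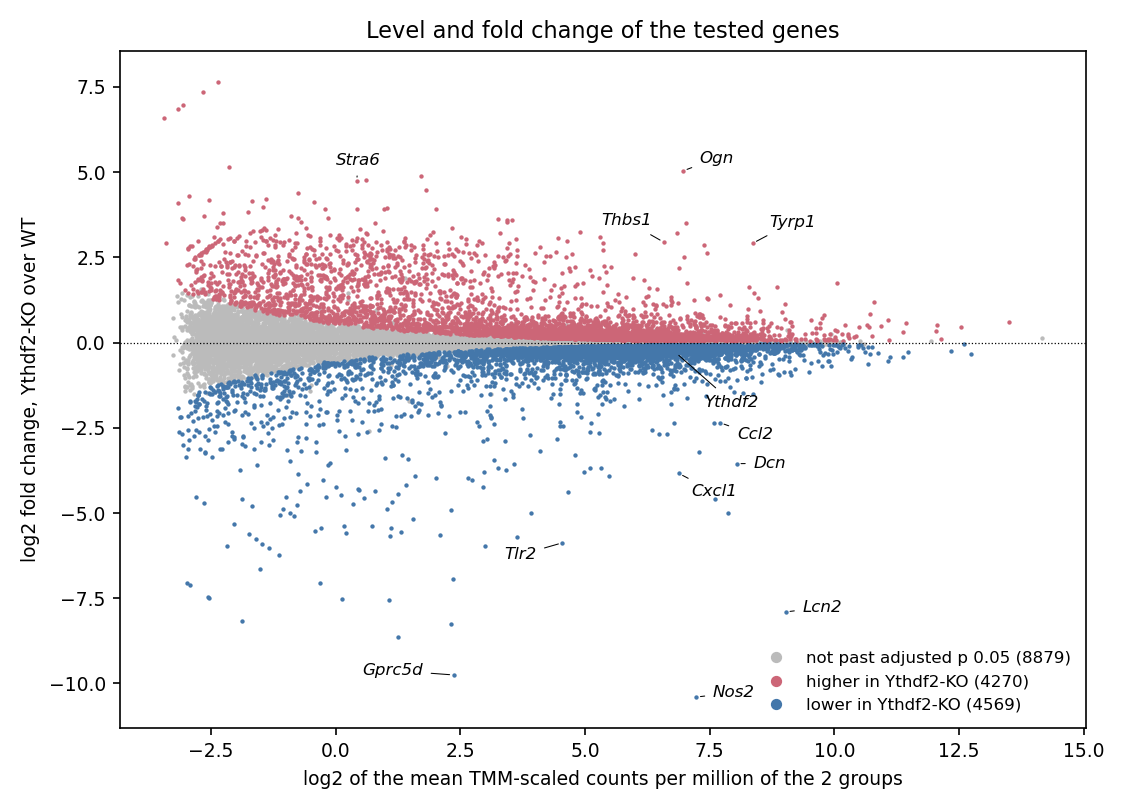
Each point is 1 of the 17718 tested genes, with the log2 of its mean TMM-scaled CPM over both groups on the horizontal axis and the fitted log2 fold change (Ythdf2-KO over WT) on the vertical axis. Red points mark the 4270 genes that were higher, blue points the 4569 that were lower and grey points the 8879 that did not pass; the large falls of Nos2 and Lcn2 and the rise of Ogn stand apart among abundant genes, and fitted values of genes near 0 counts in one group are not bounds.

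Among the 10 largest rises of genes with a mean of at least 100 counts in the higher group, Ogn, which encodes the matrix proteoglycan osteoglycin, stood out by its level. It rose 32.9-fold, from 7.37 ± 0.503 CPM in WT to 243 ± 5.66 CPM in Ythdf2-KO (SD, n = 3). The other 9 started from less than 0.5 CPM in WT. Plac8 rose 29.8-fold to 6.37 CPM, Tprg 27.4-fold to 2.95 CPM, and Slc40a1, which encodes the iron exporter ferroportin, 22.4-fold to 6.67 CPM. Stra6, which encodes a retinol transporter, rose 26.6-fold to 2.58 CPM. Rarb, which encodes a retinoic acid receptor, rose 15.1-fold to 7.55 CPM, and Aldh1a7 and Aqp8 rose 15.1- and 14.98-fold. Ccr7 and Ighm, a chemokine receptor and an immunoglobulin heavy chain better known from lymphocytes, rose 15.6- and 15.01-fold to 3.86 ± 0.0683 and 3.68 ± 0.254 CPM. Ptprc, the pan-leukocyte marker, had 2, 0 and 74 counts in Ythdf2-KO replicates 1, 2 and 3, and 2 to 6 counts in the WT libraries.

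The 10 largest falls, taken by the same minimum, included very abundant WT transcripts. Nos2, which encodes inducible nitric oxide synthase, fell from 301 ± 1.58 to 0.221 ± 0.0140 CPM (SD, n = 3), 1351-fold. Slc7a2, which encodes a transporter of arginine, fell from 4.76 ± 0.118 CPM to 2 counts over the Ythdf2-KO libraries together, a ratio of 475 (95% counting interval 131 to 3926). Lcn2, which encodes the siderophore-binding protein lipocalin 2, fell 239-fold, from 1042 ± 15.03 to 4.36 ± 0.206 CPM. The acute-phase gene Saa3 fell 63.0-fold, the neutrophil-attracting chemokine gene Cxcl5 123-fold and Tlr2, which encodes an innate immune receptor, 58.6-fold, from 46.0 ± 0.0910 to 0.781 ± 0.0328 CPM. Slc16a9 fell 189-fold from 4.16 CPM to 4 counts over the Ythdf2-KO libraries. Gprc5d, Grm7 and Tnip3 also had 2 counts each over the Ythdf2-KO libraries, against 10.3, 2.18 and 1.59 CPM in WT. Their ratios were 1023 (95% counting interval 283 to 8450), 218 (interval 60.02 to 1808) and 160 (interval 44.01 to 1330). The 2 counts of each of Gprc5d, Slc7a2, Grm7 and Tnip3 may be the 2 reads of 1 pair, which would make their intervals too narrow. They lay in 1 Ythdf2-KO library for each gene, replicate 3 for Gprc5d, 1 for Slc7a2 and Grm7 and 2 for Tnip3. Without that library the group held 0 counts, and the fall was at least 223-, 104-, 47.5- and 36.4-fold against a floor of 3 counts per library. Without replicate 3 of both genotypes, the log2 fold change of Slc16a9 went from -7.57 to -6.94 and that of Grm7 from -7.52 to -6.93.

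**Figure D2:**
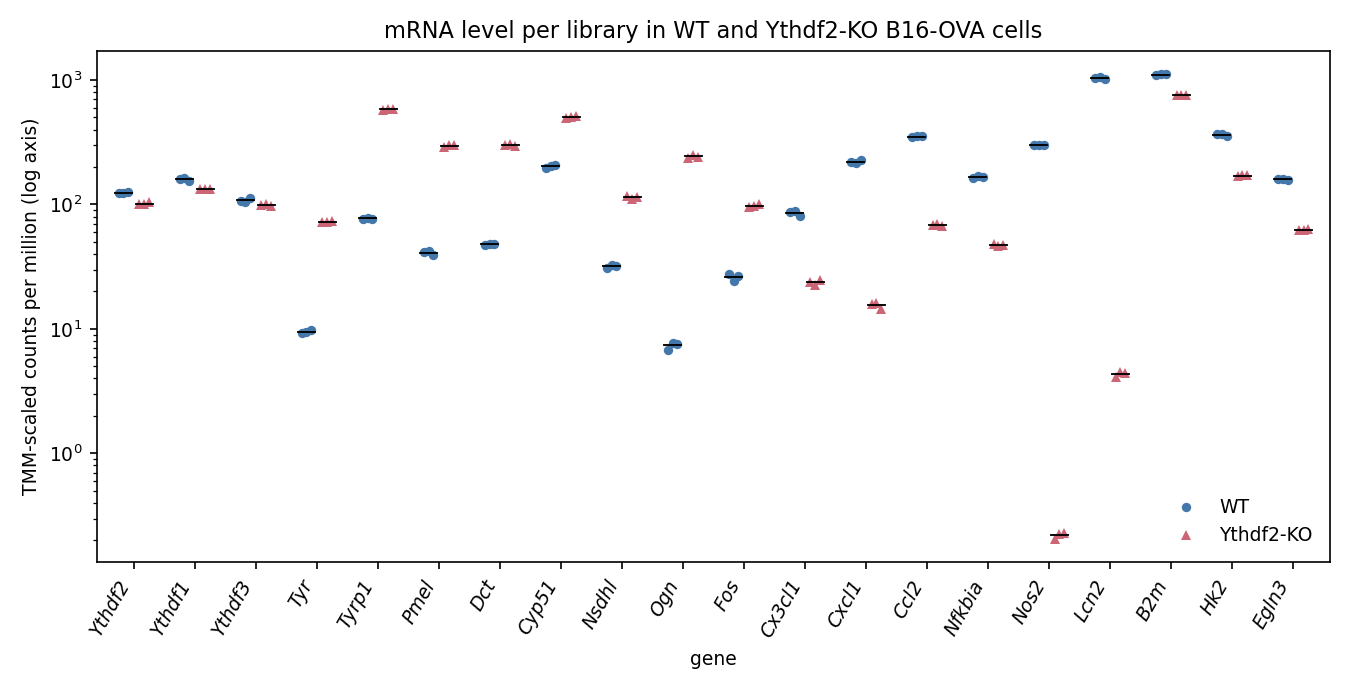
TMM-scaled CPM on a log axis for 20 genes, 1 point per library (circles WT, triangles Ythdf2-KO; 3 libraries each), with a black line at each group mean. Points of a genotype nearly coincide: Tyrp1 lies at 77.2 CPM in WT and 582 CPM in Ythdf2-KO, Nos2 at 301 and 0.221 CPM, and Ythdf2 at 124 and 101 CPM.

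Of 25 gene lists, 14 differed between the genotypes, 4 higher and 10 lower in Ythdf2-KO, by limma's camera with a preset correlation between genes of 0.01. With an estimated correlation, 5 calls remained: melanocyte and pigmentation genes, chemokines and cytokines, interferon-stimulated genes, hypoxia response, and G2/M and mitosis. With the preset correlation, camera also called 6 to 15 lists in the other 9 ways to divide the 6 libraries into 3 and 3. Each of those divisions held unequal numbers of the genotypes on its sides, so part of the genotype difference remained. Their calls do not show how often camera calls lists without such a difference. List calls are given beside counts of single genes. Member counts below are over all genes tested. Counts adjusted over the list alone were the same except where given. Members named because 5 or fewer of a list moved one way were chosen after their values were seen.

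**Figure D3:**
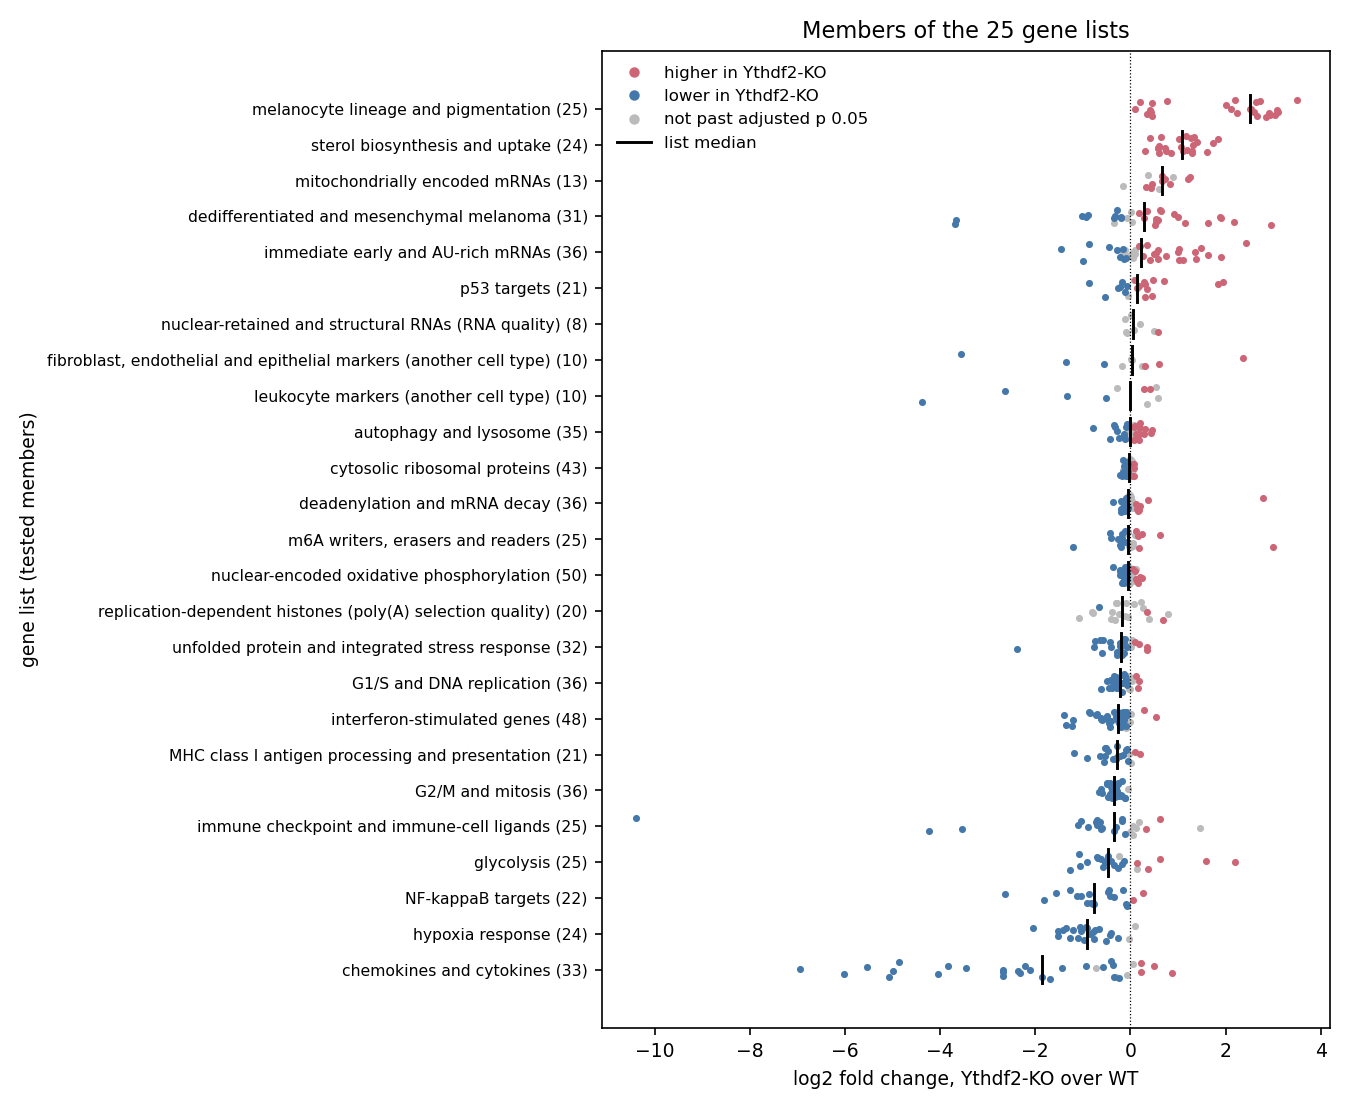
Fitted log2 fold change (Ythdf2-KO over WT) of each tested member of the 25 gene lists, 1 point per gene, with red and blue for members higher and lower at an adjusted p under 0.05, grey for the rest and a black bar at each list's median. Pigmentation genes (median 2.51) and sterol genes (median 1.09) lie to the right of 0, and chemokines and cytokines (median -1.85) and hypoxia genes (median -0.92) to the left.

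Genes of the melanocyte lineage and of pigmentation rose as a block: all 25 tested members were higher in Ythdf2-KO, with a median log2 fold change of 2.51. Tyr, which encodes tyrosinase, the rate-limiting enzyme of melanin synthesis, rose 7.65-fold from 9.50 ± 0.273 to 72.7 ± 0.968 CPM (SD, n = 3). The melanogenic enzyme genes Tyrp1 and Dct rose 7.54- and 6.24-fold, and Pmel, which encodes a melanosome structural protein, 7.25-fold. Mitf, which encodes the lineage's master transcription factor, rose 1.27-fold, from 42.9 ± 0.466 to 54.4 ± 1.78 CPM. The list was higher by camera (limma, adjusted p = 1.33e-15; adjusted p = 0.0220 with an estimated correlation).

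Genes of the dedifferentiated and mesenchymal melanoma state went both ways. Of 31 tested, 17 rose and 10 fell (adjusted over the list alone, 17 and 11), with a median log2 fold change of 0.28. The collagen gene Col1a1 rose 4.56-fold to 193 ± 4.27 CPM and Thbs1, which encodes the matrix protein thrombospondin 1, 7.71-fold to 169 ± 1.41 CPM (SD, n = 3). The gelatinase genes Mmp2 and Mmp9 each fell 12.8-fold, from 74.5 ± 1.96 and 63.8 ± 1.91 CPM. The list did not pass (camera in limma, adjusted p = 0.0866; adjusted p = 0.486 with an estimated correlation), but it passed without Ythdf2-KO replicate 3 (camera in limma, adjusted p = 0.0468) and with no filter on low counts (camera in limma, adjusted p = 0.0359), and was higher by fry (2.73e-04). Of 10 tested markers of fibroblasts, endothelium and epithelium, Pdgfra, Col6a3 and Fap rose and Dcn, Lum and Cdh5 fell. Dcn, which encodes the proteoglycan decorin, fell 11.7-fold from 487 ± 8.10 CPM, while Pdgfra rose 1.51-fold to 407 ± 6.64 CPM. The median of this list was 0.028, its mean -0.20, and camera (upward, adjusted p = 0.980 in limma) differed in sign from the mean and from fry (downward, 8.29e-06).

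Chemokine and cytokine genes fell strongly. Of 33 tested, 25 were lower and 4 higher (adjusted over the list alone, 26 and 4), with a median log2 fold change of -1.85. Cxcl1, which encodes a neutrophil attractant, fell 14.3-fold from 221 ± 4.69 to 15.4 ± 0.821 CPM (SD, n = 3). Ccl2 and Ccl7, which encode monocyte attractants, fell 5.11- and 6.37-fold, and the cytokine gene Lif 6.42-fold. Cx3cl1, which encodes fractalkine, fell 3.61-fold, from 85.8 ± 3.85 to 23.7 ± 1.11 CPM. The members that rose were Il18, Il34, Tgfb2 and Tgfb3, with log2 fold changes of 0.88, 0.22, 0.50 and 0.22. The list was lower by camera (limma, adjusted p = 5.10e-09; adjusted p = 0.0220 with an estimated correlation).

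Targets of NF-kappaB, the transcription factor family behind much inflammatory gene expression, fell alongside: 20 of 22 were lower, with a median log2 fold change of -0.77. Tnfaip3 and Nfkbia, which encode feedback inhibitors of the pathway, fell 6.19- and 3.51-fold, to 9.49 ± 0.716 and 47.2 ± 0.912 CPM (SD, n = 3). Sod2 fell 2.96-fold and Nfkb1 1.72-fold. Cflar and Ccnd1 rose, by log2 fold changes of 0.26 and 0.053. The list was lower by camera (limma, adjusted p = 4.28e-08), but not with an estimated correlation (adjusted p = 0.0666). Of 10 tested leukocyte markers, S100a8, Cd14, Cd68 and Adgre1 fell and Laptm5 and Lyz2 rose (adjusted over the list alone, 4 and 3). S100a8, which encodes a calprotectin subunit, fell 20.8-fold from 48.2 ± 1.34 CPM. This list did not pass by camera (limma, adjusted p = 0.445), but was lower by fry (5.18e-04).

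Immune checkpoint and immune-cell ligand genes were mostly lower, with 17 of 25 down and 2 up (adjusted over the list alone, 17 and 3) and a median log2 fold change of -0.34. Besides Nos2, which is also a member, Fas, which encodes a death receptor, fell 18.7-fold from 14.7 ± 0.811 to 0.787 ± 0.118 CPM (SD, n = 3). Cd47, which encodes a signal against phagocytosis, fell 1.63-fold and Lgals3 1.51-fold. Lgals1 and Ceacam1 rose, with log2 fold changes of 0.34 and 0.63. Cd274, which encodes the checkpoint ligand PD-L1, was at 7.94 ± 0.344 CPM in WT and 8.30 ± 0.283 CPM in Ythdf2-KO and did not pass the test (edgeR adjusted p = 0.570). The list was lower by camera (limma, adjusted p = 2.50e-04), but not with an estimated correlation (adjusted p = 0.0534).

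Interferon-stimulated genes fell more modestly: 39 of 48 were lower, with a median log2 fold change of -0.26. Ifi44, Gbp2 and Gbp3 fell 2.64-, 2.55- and 2.34-fold, and Ifitm3, which encodes an inhibitor of virus entry, 1.54-fold from 448 ± 7.07 CPM (SD, n = 3). Oas2 and Herc6 rose, with log2 fold changes of 0.55 and 0.29. The list was lower by camera (limma, adjusted p = 2.78e-11; adjusted p = 0.0220 with an estimated correlation). Of 21 genes of MHC class I antigen processing and presentation, 17 fell, with a median log2 fold change of -0.27. B2m, which encodes the invariant light chain of MHC class I, fell 1.45-fold, from 1105 ± 13.7 to 764 ± 0.418 CPM. H2-K1, H2-D1 and H2-Q4, whose near-identical sequences can share reads, fell 1.46-, 1.44- and 2.26-fold. Canx and Tap2 rose, with log2 fold changes of 0.21 and 0.11. This list was lower by camera (limma, adjusted p = 1.70e-05), but not with an estimated correlation (adjusted p = 0.205).

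Sterol biosynthesis and uptake genes, which are controlled together by SREBP2, all rose: 24 of 24 were higher, with a median log2 fold change of 1.09. Nsdhl rose 3.58-fold, and Cyp51 rose 2.49-fold from 202 ± 6.51 to 503 ± 6.19 CPM (SD, n = 3). Msmo1 rose 2.45-fold. The list was higher by camera (limma, adjusted p = 6.70e-17), but not with an estimated correlation (adjusted p = 0.0736).

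Hypoxia-response genes fell in the opposite direction: 22 of 24 were lower, with a median log2 fold change of -0.92. Ndrg1 and Ero1a fell 2.89- and 2.87-fold, and Egln3, which encodes an oxygen-sensing prolyl hydroxylase, 2.54-fold from 159 ± 1.62 to 62.7 ± 0.941 CPM (SD, n = 3). Hif1a and Lox, with log2 fold changes of -0.032 and 0.098, did not pass. The list was lower by camera (limma, adjusted p = 9.81e-14; adjusted p = 0.0220 with an estimated correlation). Of 25 glycolysis genes, 18 fell and 5 rose (adjusted over the list alone, 18 and 6), with a median log2 fold change of -0.47. Hk2, which encodes a hexokinase, fell 2.12-fold, from 362 ± 8.27 to 171 ± 2.14 CPM, and Ldha, which encodes a lactate dehydrogenase subunit, 1.45-fold, from 2575 ± 46.9 to 1774 ± 39.0 CPM. Slc16a3, which encodes a lactate exporter, fell 1.88-fold. Slc2a1, which encodes a glucose transporter, and Pfkfb3, members of both lists, fell 2.07- and 2.40-fold. The members that rose were Slc2a3, Aldoc, Pfkfb4, Ldhb and Slc16a1, with log2 fold changes of 2.21, 1.60, 0.63, 0.36 and 0.13. The glycolysis list was lower by camera (limma, adjusted p = 5.57e-05), but not with an estimated correlation (adjusted p = 0.246).

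Mitochondrially encoded mRNAs rose in part: 9 of 13 were higher and none lower (adjusted over the list alone, 10 higher), with a median log2 fold change of 0.66. mt-Nd1 rose 1.77-fold from 1216 ± 130.3 to 2158 ± 148 CPM and mt-Cytb 1.58-fold from 1680 ± 162 to 2655 ± 223 CPM (SD, n = 3); with the replicate block mt-Cytb did not pass (edgeR adjusted p = 0.0708). mt-Nd1 stood at 1203, 1093 and 1353 CPM in WT replicates 1 to 3 and at 2241, 2246 and 1987 CPM in Ythdf2-KO replicates 1 to 3. Malat1, a nuclear-retained RNA among the measures of RNA quality, ranked the libraries in the same order, at 431, 376 and 511 CPM in WT and 689, 722 and 576 CPM in Ythdf2-KO. mt-Atp8 and mt-Co2 rose 2.39- and 1.26-fold, from 0.370 and 15.8 CPM, low levels for mRNAs that can share reads with nuclear copies. mt-Nd3, mt-Nd6, mt-Co3 and mt-Atp6 did not pass, with log2 fold changes of 0.89, 0.38, 0.60 and -0.16. The list was higher by camera (limma, adjusted p = 4.44e-04), but not with an estimated correlation (adjusted p = 0.419). Among 50 nuclear-encoded oxidative phosphorylation genes, 23 fell and 7 rose (adjusted over the list alone, 23 and 8), all by small amounts: Uqcrfs1, Cox8a and Cox6a1 fell 1.28-, 1.16- and 1.15-fold and Ndufa4 rose 1.18-fold. That list did not pass by camera (limma, adjusted p = 0.151), but was lower by fry (0.0322).

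Cell-cycle genes were lower. Of 36 G2/M and mitosis genes, 35 fell, with a median log2 fold change of -0.33, and Bub1b, at -0.046, did not pass. Aurka, which encodes a mitotic kinase, fell 1.58-fold from 137 ± 2.32 to 87.0 ± 1.34 CPM (SD, n = 3), Ube2c and Bub1 fell 1.52- and 1.504-fold and Tpx2 1.41-fold. The list was lower by camera (limma, adjusted p = 1.55e-13; adjusted p = 0.0220 with an estimated correlation). Of 36 G1/S and DNA replication genes, 27 fell, with a median log2 fold change of -0.22, among them Rrm2, Mcm5, E2f1 and Mcm7 by 1.54-, 1.29-, 1.33- and 1.26-fold. E2f8, E2f2 and Mcm2 rose, with log2 fold changes of 0.18, 0.16 and 0.12. This list was lower by camera (limma, adjusted p = 8.34e-06), but not with an estimated correlation (adjusted p = 0.0906). Of 21 p53 targets, 12 rose and 7 fell: Trp53inp1, Ccng1 and Zmat3 rose 3.60-, 1.397- and 1.37-fold and Plk2 fell 1.83-fold (camera in limma, adjusted p = 0.275).

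Immediate early and AU-rich mRNAs went both ways with more up than down, 20 against 9 of 36 (adjusted over the list alone, 22 and 9). Fos rose 3.75-fold from 26.1 ± 1.58 to 97.9 ± 2.44 CPM (SD, n = 3), and Dusp1 and Zfp36, which encode a phosphatase and an mRNA-destabilizing protein, 2.82- and 2.55-fold. Ier3 fell 2.73-fold. Myc, at 76.4 ± 3.25 and 77.7 ± 3.48 CPM, did not pass, and without replicate 3 of Ythdf2-KO its log2 fold change went from 0.026 to -0.011; with upper-quartile scaling Myc was called higher (edgeR adjusted p = 0.0407). The list was higher by camera (limma, adjusted p = 0.00704), but not with an estimated correlation (adjusted p = 0.477). Genes of the unfolded protein and integrated stress responses were mostly lower, with 23 of 32 down and a median log2 fold change of -0.19. Slc7a11, which encodes the cystine importer, fell 5.18-fold from 185 ± 0.775 to 35.8 ± 1.61 CPM. Cebpb, Herpud1 and Hspa5 fell 1.68-, 1.495- and 1.35-fold, and Ppp1r15a, Xbp1, Sesn2 and Phgdh rose, with log2 fold changes of 0.36, 0.35, 0.19 and 0.10. This list was lower by camera (limma, adjusted p = 2.05e-04), but not with an estimated correlation (adjusted p = 0.363).

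Other genes of the m6A pathway went both ways, where 49.9% of all tested genes differed. Of 25 tested writers, erasers and readers other than Ythdf2, 6 rose and 11 fell (adjusted over the list alone, 6 and 12), with a median log2 fold change of -0.049 and a mean of 0.035. The m6A reader genes Igf2bp1 and Igf2bp2 moved apart: Igf2bp1 rose 7.96-fold from 0.578 ± 0.106 to 4.62 ± 0.599 CPM and Igf2bp2 fell 2.31-fold from 78.3 ± 2.25 to 33.9 ± 0.865 CPM (SD, n = 3). Alkbh5, which encodes an m6A eraser, and Hnrnpc fell 1.34- and 1.33-fold. Of 36 genes of deadenylation and mRNA decay, 7 rose and 14 fell (adjusted over the list alone, 7 and 15), with a median of -0.044 and a mean of 0.046. Dcp1b, which encodes a decapping cofactor, rose 6.91-fold from 0.212 ± 0.128 to 1.53 ± 0.185 CPM, Ddx6 rose 1.11-fold, and Cnot7 fell 1.28-fold. Neither list passed by camera (limma, adjusted p = 0.286 for both), but both were lower by fry (limma, adjusted p = 3.31e-05 and 0.00468).

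The remaining lists did not pass either. Of 35 autophagy and lysosome genes, 15 rose and 11 fell, Ctsd rising 1.36-fold and Npc2, Ctsl and Sqstm1 falling 1.72-, 1.35- and 1.27-fold (camera in limma, adjusted p = 0.661); the median was -0.0083, the mean 0.0050 and camera pointed up. Of 43 cytosolic ribosomal protein genes, many with near-identical pseudogenes, 19 fell and 5 rose, with a median of -0.037; camera turned from down to up with upper-quartile scaling (limma, adjusted p = 0.857). Rpl5, Rpl34, Rps25 and Rpl4 fell 1.16-, 1.12-, 1.11- and 1.10-fold, and Rpl3, Rplp0, Rps2, Rps20 and Rpsa rose by log2 fold changes of 0.059 to 0.084 (camera in limma, adjusted p = 0.166). Of 20 replication-dependent histone genes, whose mRNAs lack poly(A) tails, H1f2 and H4c9 rose 1.61- and 1.28-fold and H1f1 fell 1.58-fold (camera in limma, adjusted p = 0.947). H1f1 did not pass when adjusted over the list alone, with DESeq2 (adjusted p = 0.130), with upper-quartile scaling or no filter (edgeR adjusted p = 0.0654 and 0.0769), or without any 1 of WT replicates 2 and 3 and Ythdf2-KO replicates 1 and 2 (edgeR adjusted p = 0.0945, 0.0988, 0.0934 and 0.226). Of 8 nuclear-retained and structural RNAs (camera in limma, adjusted p = 0.513), Malat1 was higher at 662 ± 76.6 against 439 ± 68.3 CPM (SD, n = 3), a call that did not hold when adjusted over the list alone, with the replicate block or no filter (edgeR adjusted p = 0.172 and 0.0699), or without any 1 of WT replicates 1 and 2 and Ythdf2-KO replicates 1 and 2 (edgeR adjusted p = 0.112, 0.0884, 0.117 and 0.117). Rn7sk, Rmrp and Gas5 had log2 fold changes of 0.20, 0.51 and 0.078 and did not pass. Rn7sk passed without Ythdf2-KO replicate 1, with no filter and with the replicate block (edgeR adjusted p = 2.71e-05, 7.63e-04 and 0.00435), and Gas5 without WT replicate 3, with no filter and with the block (edgeR adjusted p = 0.00421, 0.00294 and 0.0335).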

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

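Leaving out both libraries with blood-cell transcripts was chosen after the data were seen; the other alternatives were chosen before. The length and GC offsets and the stricter adjusted p were run for the counts of called genes, not for single named genes or lists. Over the genes named by rule and the other alternatives, 1845 results kept direction and side of the threshold, 16 lost their call, 7 gained one and 3 changed direction. For lists, which DESeq2 and limma-voom did not test, these numbers were 344, 9, 7 and 13. Without each library in turn, 3937 to 4270 genes were higher and 4158 to 4387 lower, and the Ythdf2 log2 fold change was -0.31 to -0.28. DESeq2 called 3939 higher and 3932 lower, and limma-voom 4271 and 4587. With the filter at a mean of 5 CPM, which removes the low genes, 239 genes were at least 2-fold higher and 171 lower. With an estimated correlation, camera in limma called 1 list higher and 4 lower, while fry called 5 higher and 15 lower. Besides the fibroblast, endothelial and epithelial list, fry called lists that camera did not: the mesenchymal list, higher (limma, adjusted p = 2.73e-04), and the m6A, decay, leukocyte and oxidative phosphorylation lists, lower (3.31e-05, 0.00468, 5.18e-04 and 0.0322). Fibroblast, endothelial and epithelial markers, not called by camera, changed direction with adjusted p = 0.964 (RLE), 0.816 (upper quartile) and 0.977 (without abundant genes), and were lower by fry at 8.29e-06. With 1 library left out (0.771 to 0.934), they turned down without each Ythdf2-KO library and stayed up without each WT library. Ribosomal proteins changed direction with upper-quartile scaling (0.857), autophagy and lysosome genes by fry (0.740), and histones by fry (0.677). With 1 library left out (0.621 to 0.887), histones turned up without WT replicate 3 (0.842) and Ythdf2-KO replicate 1 (0.814) and stayed down otherwise. Myc had log2 fold changes of -0.011 to 0.064 over libraries left out, negative without Ythdf2-KO replicate 3, and -0.027 without both libraries with blood-cell transcripts, where Rmrp had -0.066; the cause of these changes in direction was not tested. Without both, 3764 genes were higher and 4184 lower, and 4 lists were higher and 10 lower.

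Same-numbered libraries of the genotypes deviated from their group means with correlations of 0.036, -0.10 and -0.15, and 1 of 3 numbers matched best with its own, so the numbers were not taken as pairs. The replicate block gave 4132 genes higher and 4409 lower and a Ythdf2 log2 fold change of -0.29. Under the block the fibroblast, endothelial and epithelial list pointed down (camera in limma, adjusted p = 0.991). There mt-Cytb and Malat1 lost their calls, and Rn7sk and Gas5 gained one (edgeR adjusted p = 0.00435 and 0.0335). The block changed no other call on a gene named by rule or on a list.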

Other observations

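The tests of gene families, chromosomes, copy number, leukocytes, fibroblasts and the mesenchymal shift, the splits for all but the total number of genes, and the removal of replicate 3 of both genotypes were chosen after the results were seen.

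Of 170 gene families that share a symbol stem, 7 were called by camera in limma, and none of the 7 with an estimated correlation (adjusted p = 0.643 for each). Some of their members, such as Mmp2, Mmp9, Ifi44, Psmb8 and Psmb9, also stand in the fixed lists. Matrix metalloproteinase genes fell, with 9 of 11 lower and a median log2 fold change of -2.12: Mmp8, Mmp10, Mmp3 and Mmp13 had log2 fold changes of -5.56, -4.74, -3.91 and -2.04 (adjusted p of the family = 1.17e-04 by camera in limma; adjusted p = 0.643 with an estimated correlation). All 10 proteasome beta-subunit genes (Psmb) fell, with a median of -0.14, and 12 of 14 regulatory-subunit genes (Psmd), with a median of -0.17. Among the Psmb genes, Psmb9 and Psmb8, which encode immunoproteasome subunits, had log2 fold changes of -0.90 and -0.47. Interferon-inducible Ifi genes fell in 9 of 14 cases and rose in 1. Semaphorin genes, which encode guidance signals, rose in 12 of 19 cases and fell in 4, with Sema7a at 2.61 and Sema3e at 2.51. The guanine exchange factor genes of the Dock family rose in 9 of 10 cases and the mannosidase genes (Man) in 7 of 10, with 1 lower in each. The family members named here were chosen after their values were seen.

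Of 20 chromosomes, 9 had a median log2 fold change apart from that of all placed genes at a permutation adjusted p under 0.05. Of these, 3 lay above and 6 below it. The permutations took genes as independent, so their p-values do not allow for neighbouring genes that vary together. Genes on chromosome 8 had a median log2 fold change of -0.095, with 140 higher and 338 lower of 842, genes on chromosome 6 a median of 0.070, with 289 higher and 163 lower of 809, and genes on chromosome 11 a median of 0.029, with 388 higher and 293 lower of 1249, against -0.011 over all placed genes (permutation p = 1e-04 for each, the smallest that 10000 permutations can give; Benjamini-Hochberg adjusted p = 6.67e-04 over 20 chromosomes).

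The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 8839 genes, 4270 higher and 4569 lower, 1092 at least 2-fold higher and 598 at least 2-fold lower. For each of these counts, 1 of the 10 divisions, the real one, reached the value. The highest other value was 0 by edgeR, with 142 to 235 genes at an unadjusted p under 0.05, and limma-voom also called 0. For gene lists, 3 of the 10 divisions called as many as the real 14, and the highest other called 15. Every other division held both genotypes on each side in unequal numbers. Part of the genotype difference therefore lay between its sides, and part added to its spread. None of these counts shows how many genes or lists would be called without a genotype difference.

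Of the tested genes, 49.9% differed between the genotypes, mostly by little. Under the scaling that kept fewest, 89.0% of the 8839 called genes kept call and direction. With offsets for length and GC content, 88.4% of the 8692 called genes with a known transcript length did so, and 31 were called in the other direction. A part from scaling or from length and GC bias therefore cannot be told apart from genotype for the small differences. Of the 1690 genes at least 2-fold apart, 99.0% were kept under the scaling that kept fewest. Of the 1637 of them with a known transcript length, 99.3% were kept with the offsets. Upper-quartile scaling moved the median log2 fold change of all tested genes only from -0.0053 to 0.049, so a 2-fold difference could hardly lose its direction. The large differences thus did not hinge on the choice among these corrections, but other effects of composition or bias are not excluded. Stretches of the genome with another copy number in one population would move neighbouring genes together. Windows of 41 neighbours counted if their median log2 fold change lay beyond all 100 permutations, below -0.270 or above 0.389. They held 0.576% of the called genes that could be placed. They formed 2 segments, on chromosome 14 (median over the segment -0.294) and on chromosome 8 from Fto to Zfp319 (-0.236). This argues against local copy-number changes with shifts of that size as the main source. Smaller or partial changes could not be seen this way, and whether copy number lay behind the shifted chromosome medians above was not tested. Whether the differences come from loss of YTHDF2 or from separately derived cell populations was not tested.

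The hypothesis that lost decay of m6A-marked mRNAs was the main source of the differences predicts higher levels of mRNAs with more GGACT, a common m6A sequence, in the 3-prime UTR. Over 12284 genes, the Spearman correlation of GGACT sites per kb with the log2 fold change was -4.35e-04 (95% bootstrap interval -0.0172 to 0.0180; permutation p = 0.961), and among the 7539 genes that differed it was -0.00255 (interval -0.0260 to 0.0202). These values argue against the hypothesis in this form, without correction for GC content or UTR length. Transcript GC content did correlate with the log2 fold change (rho 0.077, permutation p adjusted over 5 correlations = 5e-04). Sequence counts do not show which sites carry m6A, and decay of a smaller set of targets was not tested.

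Pigmentation genes were higher and chemokine, cytokine and NF-kappaB target genes lower in Ythdf2-KO. Leukocytes in the WT cultures would bring all their abundant transcripts: S100a8, Cd14 and Cd68, at 48.2, 23.8 and 20.4 CPM in WT, fell as this predicts, but the median of 24 leukocyte markers in WT was 0.0748 CPM, with Ptprc at 0.0916 CPM or less and S100a9 and Tyrobp at means of 0.0340 and 0.00973 CPM, which argues against leukocytes. Fibroblasts would have to give at least 82.5% of the WT RNA to dilute the pigmentation genes by their median fold. Yet 5 of 7 abundant fibroblast transcripts (Pdgfra, Col6a3, Col3a1, Col1a1 and Col1a2) were higher in Ythdf2-KO, with Col1a2 at 2.46 CPM in WT and 9.08 CPM in Ythdf2-KO. The 7 were chosen after the results were seen and 2 of them fell, so their count is no independent test. For so large a share of the WT RNA, the 5 that rose argue against fibroblasts as the source of the pigmentation difference. A smaller share of fibroblasts in WT stays open for the lower inflammatory genes, because 2 of the 7, Dcn and Lum, fell with them, although Col1a2 rose. A shift of the tumor cells from a mesenchymal to a melanocytic state stays open, because the mesenchymal list had a median log2 fold change of 0.28 (95% bootstrap interval -0.19 to 0.57) over members that went both ways, and a lower inflammatory state of the Ythdf2-KO population, from the genotype or from culture, is a hypothesis that these data did not test.

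Blood-cell transcripts stood out in 2 libraries. Of 38 lymphoid genes, 73.7% were highest in replicate 3 among the Ythdf2-KO libraries (exact binomial p = 6.34e-07 against 1 in 3). That library had 74 counts of Ptprc and 43 of Ms4a4b, as traces of lymphoid RNA would give. Of the 38 genes, 9 reached a mean of 1 CPM in the other libraries, and their summed raw counts were 5221, 4722 and 5802 in Ythdf2-KO replicates 1 to 3. The binomial test takes genes as independent, so its p-values in this paragraph do not allow for genes that vary together. Of 25 erythroid and platelet genes, 52% were highest in WT replicate 3 (exact binomial p = 0.0564), where Hbb-bs had 512 counts against 5 and 8 in the other WT libraries, so traces of red-cell RNA there stay open; Ythdf2-KO replicate 3 had 66 counts of Hbb-bs against 4 and 6 in the other Ythdf2-KO libraries, and 35 of Hba-a1 against 5 and 14. The source of such traces was not tested. Without both libraries 3764 genes were higher and 4184 lower.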
